A study of Mus musculus with 36 samples.

How the data were processed

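H3K27ac ChIP-seq peak lists of 18 libraries from forelimbs of mouse embryos at embryonic day 11.5 were used, 1 list per library. The 18 matched input samples were not used here. Groups and replicate numbers came from the labels. Per the submitters' processing notes, the tools named were CASAVA, bcl2fastq 2.17, cutadapt 1.1, Bowtie 0.12.8 and MACS 1.4.2, and the genome build was mm9. Whether the inputs served as control in peak calling was not given in the sources used here. Each deposited list gives a position and a score per peak, and the authors' scores ran from 40 to 3233. The score is the peak's own value, and it was used only to filter peaks or to rank them within a list, as a percentile. The lists hold no read counts, so depth is unknown, no interval for counting error was computed, and a missing peak shows that a call was not made, not that the mark was absent. Deeper libraries can yield more and wider peaks from the same tissue.

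A run tag attached to the lists, which the labels do not give, divided the libraries into 4 technical batches. No lists were identical. Libraries are of pooled tissue, and p-values of comparisons between libraries measure only their spread, which may be technical. Those of the tests of neighbouring regions take regions as the unit and do not measure that spread.

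Consensus regions were stretches covered by peaks of at least 2 of the 18 libraries, and a library called a region if a peak overlapped it by at least 1 bp. For the search for gaps, the genome was divided into tiles of 500 bp, called when peaks covered at least 250 bp. A lost segment was a run of adjacent tiles called in every other library and in no library of a line, and a gained segment the opposite. Counts were ranked among sets of as many libraries of mixed genotype from the same runs. Retention was the percentage of regions called by 3 wild-type libraries that a library also called, averaged over the choices of 3, and a wild-type library was scored on the other 3. Similarity was the Jaccard index of covered bases.

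The mm1179 and wild-type libraries were compared by exact two-sided permutation tests of 70 arrangements, and per region by Fisher's exact test with Benjamini-Hochberg adjustment. Genotype labels were permuted 100000 times for the similarity. Alternatives were a minimum score of 100, the 26550 highest-scoring peaks of each list, tiles of 1000 bp, 90% of the other libraries in place of all (10% for gained segments), coverage of a larger part of a region, regions of 1 library, autosomes, the replicate number as a block, arrangements within runs and leaving out each replicate. Leaving out run 3, the length of the longest segment and equal lists with labels permuted within runs were chosen after seeing the data, as were the tests of the neighbouring regions, of the regions missed in run 3 and of exchanged labels, with their bounds. The main comparisons, their tests and the other alternatives were fixed before the data were examined.

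Named segments were the 3 lost and 3 gained per line (5 for mm1179) with most tiles, ties going to the higher mean score percentile. Named regions were the 10 with the highest percentile in each direction between mm1179 and wild type, and the 10 highest in wild type. The few that matter are given in full. The annotation table at hand was of GRCm38, another build than mm9, so no gene was assigned to a region. The planned comparison of promoter peaks over fixed gene lists was therefore not run, and those lists are not reported.

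The procedures were tested on simulated data, with 200 deletions of 2 kb planted in the real tile calls of each line. Sites were taken only where every wild-type library called the tiles, and all planted tiles of the line were set to uncalled. A deletion counted as recovered if any of its tiles was lost. The share recovered as lost in the line alone was 52.0% for mm1179, 51.0% for hs72, 51.5% for hs1262, 52.0% for hs1467, 52.5% for hs1586 and 62.5% for hs1603. Without run 3 it was 100.0% for mm1179 and 99.0% for each other line, with only replicate 2 left of hs1262, hs1467, hs1586 and hs1603. Under these rules the share shows only how often the other libraries called the planted tiles. Peaks that bridge a deletion were not simulated, nor were enhancers that some wild-type library did not call. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Coordinates are 1-based, in mm9.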

Results

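Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active enhancers and promoters, was profiled by ChIP-seq in forelimbs of mouse embryos at embryonic day 11.5. Wild-type forelimbs were compared with forelimbs of 6 lines, each carrying a knockout of a limb enhancer named mm1179, hs72, hs1262, hs1467, hs1586 or hs1603. The comparison asks what the loss of a single enhancer does to the enhancer landscape of the limb. There were 4 wild-type libraries, 4 mm1179 libraries and 2 libraries of each of the other 5 lines, 18 in all. Each library had its own deposited peak list, so the library was the unit of the comparisons between genotypes. Tests of regions near lost segments, and the interval for regions missed in run 3, took regions as the unit. Read depth was unknown, since the lists hold no read counts. The peak lists carried 4 run tags, used here as technical batches and called runs 1 to 4. Run 1 held WT and mm1179 replicates 1 and 2. Run 2 held WT and mm1179 replicates 3 and 4 and both hs72 libraries. Runs 3 and 4 held replicate 1 and replicate 2, respectively, of hs1262, hs1467, hs1586 and hs1603, and no wild-type library. For those 4 lines, run and genotype cannot be told apart in any comparison with wild type.

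Wild-type forelimbs had 39420 ± 3640 peaks (SD, n = 4), which covered 86.2 ± 11.2 Mb of the genome (SD, n = 4). The lists merged into 63594 consensus regions over all 18 libraries. All 4 wild-type libraries called 23161 of these regions, and 970 of them were at least 10 kb wide. All 18 libraries called 10497 regions, or 45.3% of those called in every wild-type library. Run 3 set most of this limit, since all 10 libraries of runs 1 and 2 called 19035 regions, of which the run 4 libraries each missed at most 0.0105% and the run 3 libraries 29.5% to 41.9%. Among the 10 wild-type regions with the highest mean score percentile, 7 were called in all 18 libraries. They included regions on chromosome 7 from 80737768 to 80744094, on chromosome 8 from 38013516 to 38017875 and on chromosome 9 from 57998489 to 58009085 (mm9). The region ranked highest, 40.8 kb on chromosome 8 from 59788858 to 59829693, was called in 14 libraries, all but those of run 3. Genes were not assigned to regions, because the annotation at hand was of another genome build.

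**Figure D1:**
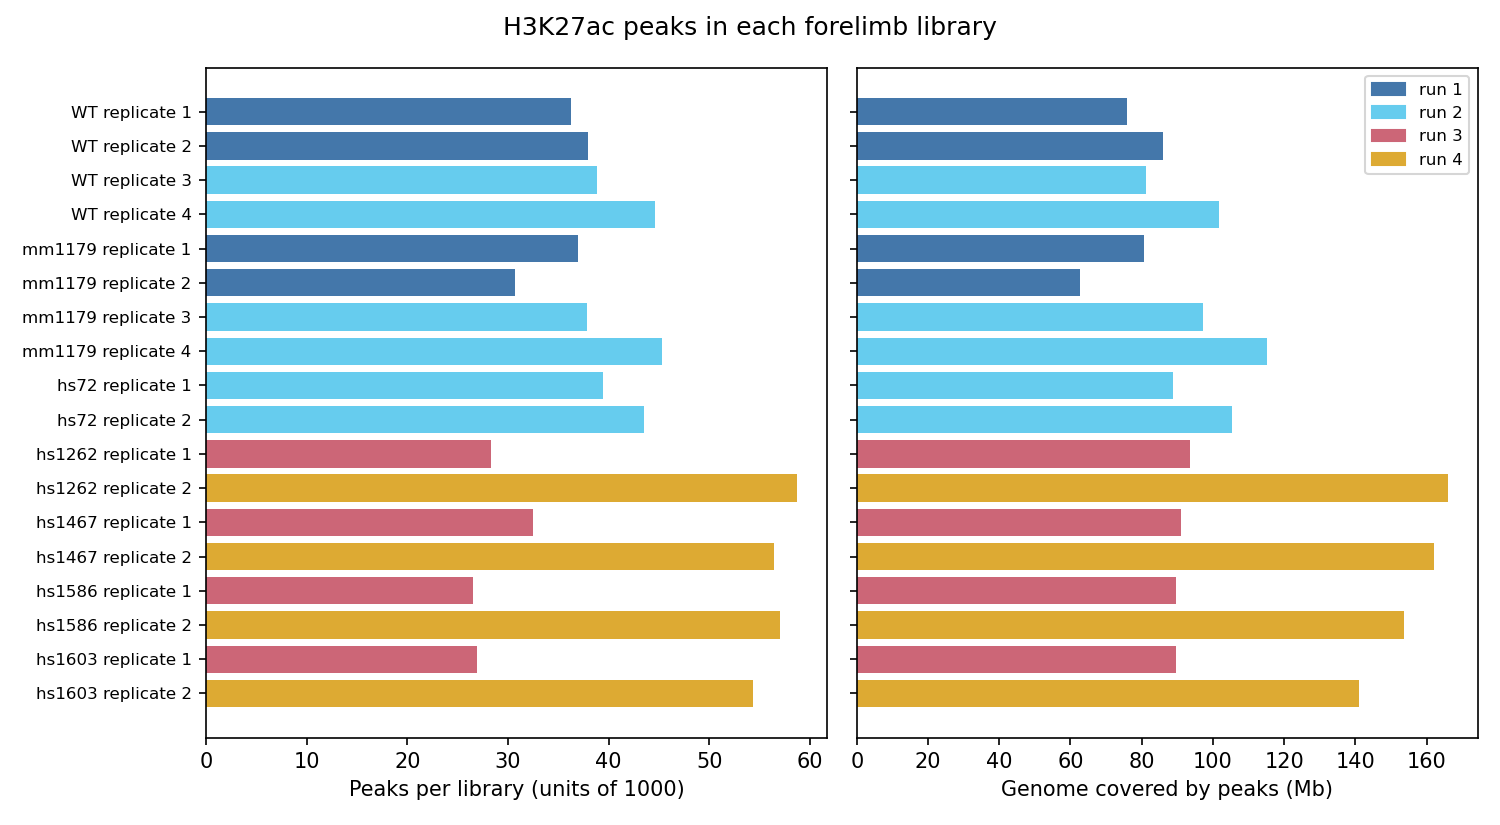
Number of peaks (left, in units of 1000) and genome covered by peaks (right, Mb) in each of the 18 libraries, 1 bar per library, coloured by run. The run 4 libraries have 54375 to 58753 peaks and the run 3 libraries of the same 4 lines 26550 to 32472.

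Forelimbs lacking mm1179, an enhancer known to act on Gli3, a transcriptional effector of Hedgehog signalling, did not differ from wild type in the amount of H3K27ac-marked sequence by more than the spread of the libraries. They had 37694 ± 5961 peaks (SD, n = 4) against 39420 ± 3640 in wild type (SD, n = 4), with p = 0.657 in an exact two-sided permutation test. The peaks covered 89.0 ± 22.5 Mb (SD, n = 4) against 86.2 ± 11.2 Mb, with p = 0.886 in the same exact test. Mean peak width was 2335 ± 265 bp (SD, n = 4) in mm1179 and 2183 ± 104 bp in wild type, with an exact p of 0.343. Of the regions called by 3 wild-type libraries, mm1179 libraries called 92.7% ± 5.6 (SD, n = 4), and a wild-type library left out of the 3 called 93.5% ± 2.8 (SD, n = 4). In run 1, mm1179 had 33832 peaks on average and wild type 37105 (exact permutation p = 0.667, n = 2 each). In run 2 the averages were 41557 and 41736 (exact permutation p = 1, n = 2 each). Covered length went opposite ways in the runs, at 71.7 Mb in mm1179 and 80.9 Mb in wild type in run 1 and at 106.3 and 91.5 Mb in run 2 (exact permutation p = 0.667 in each, n = 2 each). So did mean peak width, at 2112 and 2178 bp in run 1 (exact permutation p = 0.667) and at 2558 and 2187 bp in run 2 (exact permutation p = 0.333). With 2 libraries against 2, no run alone could pass the threshold. The sign of the peak difference turned without WT replicate 4, with 16.2 more peaks in mm1179, and without mm1179 replicate 2, with 599 more. The mm1179 minus wild-type difference in covered length was -0.731 Mb without WT replicate 1 and -6.05 Mb without mm1179 replicate 4.

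Region by region, 42 consensus regions were called in all 4 wild-type and no mm1179 library, and 19 in all 4 mm1179 and no wild-type library. The 42 were mostly narrow and weak, with a median width of 2151 bp and a median score percentile of 20.03. The 19485 regions called in all 8 libraries had a median width of 3665 bp and a median percentile of 71.2. The strongest region found only in wild type lay on chromosome 2 from 52911356 to 52914282, at a mean percentile of 76.1. Next came regions on chromosome 11 from 32117656 to 32119692 and from 113525301 to 113530509, at percentiles of 38.0 and 31.4. The strongest found only in mm1179 lay on chromosome 5 from 13057863 to 13060919 (percentile 47.5) and on chromosome 11 from 51606142 to 51608803 (percentile 31.9). All 5 regions were also called in some libraries of the other knockout lines.

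None of the 54583 regions tested passed Benjamini-Hochberg adjustment in Fisher's exact test, where 61 had an unadjusted p under 0.05. The smallest p that 4 against 4 libraries can give is 0.0286, so no region could have passed. Of 3657 regions called in exactly 4 of these 8 libraries, random labels would separate 2.86%, or 104.5 regions, against the 61 observed. That value moves labels across runs. The 18 splits that keep both runs balanced, as the genotypes are, separated 69.1 regions on average, the real split included, so 61 lay near chance. With 1 library left out, which can only raise the counts, the wild-type-only count was between 53 and 196, highest without mm1179 replicate 4, and the mm1179-only count between 25 and 156, highest without mm1179 replicate 2.

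Lost segments, short gaps that by definition lie where all other libraries have peaks, were found in 5 of the 6 lines. The search was meant for deleted enhancers, since deleted DNA leaves no reads, so a gap does not by itself show lost acetylation. In mm1179 the longest gap was 3 kb on chromosome 13 from 15434001 to 15437000, with peaks in all 14 other libraries at a mean score percentile of 90.2. Peaks remained on both sides of it in mm1179 replicates 1, 3 and 4. In hs1586, also known as a limb enhancer of Gli3, the gap was 2 kb on chromosome 13 from 15640501 to 15642500 (percentile 86.6), 203.5 kb from the mm1179 gap. In hs1603 it was 3.5 kb on chromosome 6 from 143446501 to 143450000 (percentile 88.6), and in the libraries labelled hs1467 it was 2.5 kb on chromosome 11 from 111688501 to 111691000 (percentile 85.4). These were the sole lost segments of hs1467, hs1586 and hs1603.

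The other lost segments were shorter. Those of mm1179 were 1.5 kb on chromosome 5 from 89013501 to 89015000 and 0.5 kb on chromosome 11 from 79079501 to 79080000. There were 30 in hs72, of which the longest was 1.5 kb on chromosome 8 from 91978001 to 91979500, at a percentile of 51.2, followed by segments on chromosome 15 from 77647501 to 77648500 and on chromosome 14 from 120712001 to 120713000. The hs72 segment on chromosome 8 was not among those lost when peaks had to score at least 100 or when lists were shortened to equal length. No segment was lost in both libraries labelled hs1262. In simulated data, 51.5% of 200 deletions of 2 kb planted in hs1262 were recovered. Without the run 3 libraries, which leaves only replicate 2 of hs1262, 198 of 200 were recovered. The planted sites were called in every wild-type library, and any lost tile counted as recovery. These shares show how often the other libraries call such sites, not how often a real deletion would be found. A count of 0 therefore leaves room for a missed deletion.

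**Figure D2:**
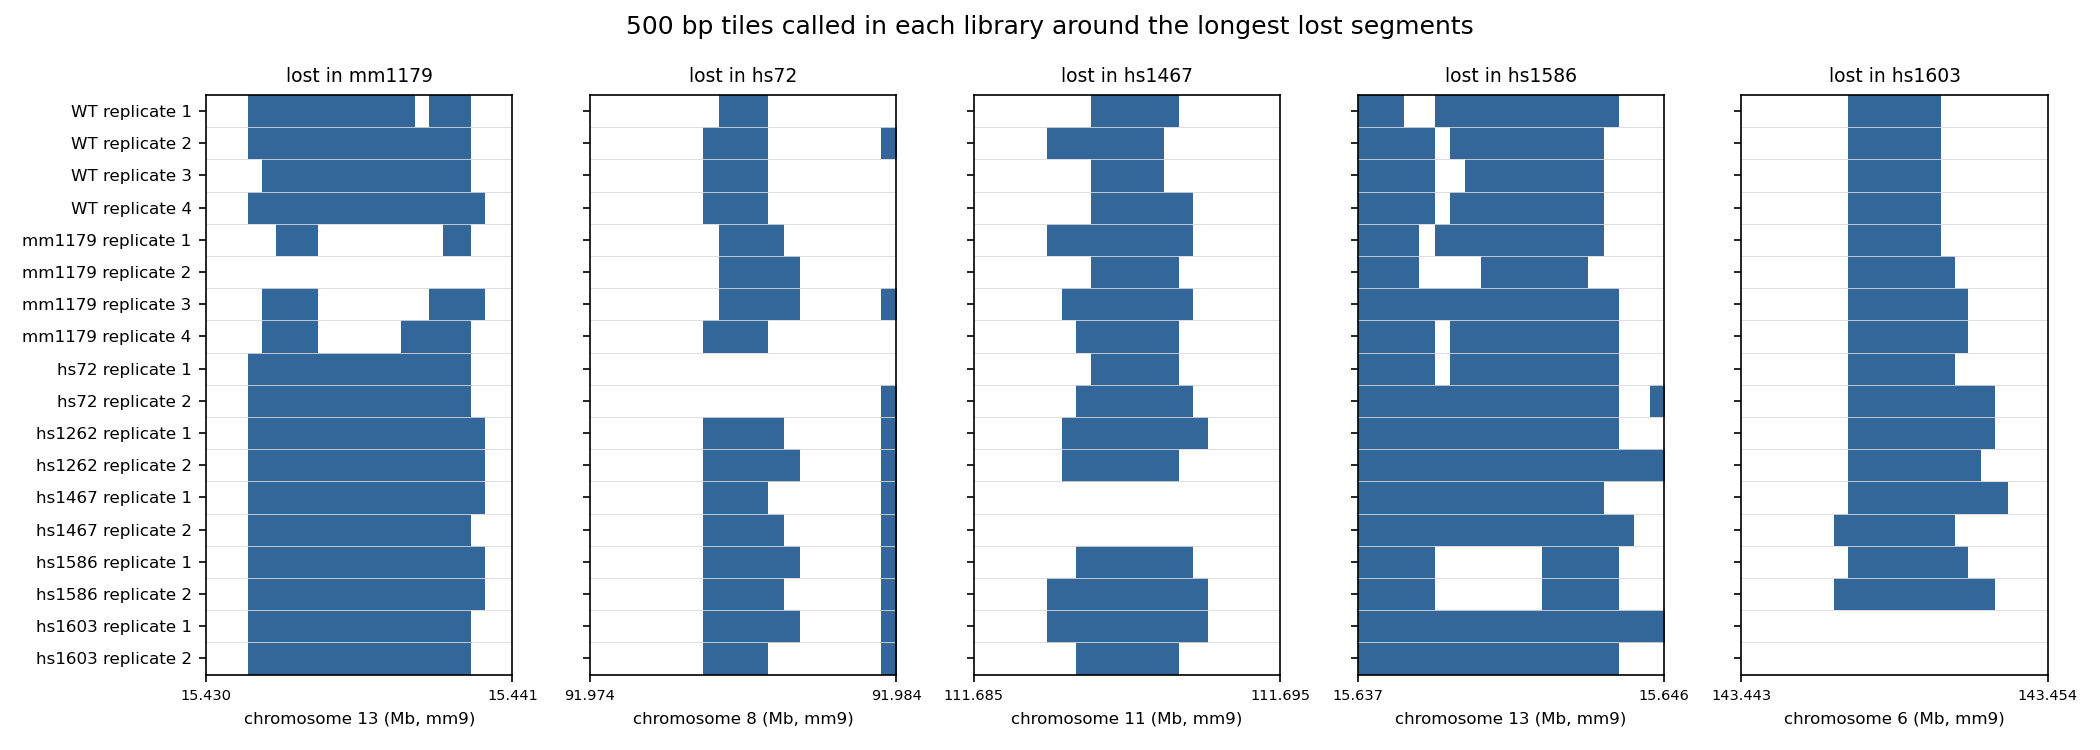
Tiles of 500 bp called (blue) or not called (white) in each of the 18 libraries around the longest segment lost in 5 lines, by position in mm9. In each panel the libraries of the named line lack the tiles that all others have, over 3 kb in mm1179 and 3.5 kb in hs1603.

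The number of lost segments did not set any line apart from sets of as many libraries of mixed genotype from the same runs. For mm1179, 83 of 88 mixed sets had at least its 3 segments (rank p = 0.944, one-sided exact). For hs72, 2 of 12 mixed sets had at least 30 (exact rank p = 0.231), and for hs1467, hs1586 and hs1603, 2 of 12 had at least 1 (exact rank p = 0.231). Those 2 were the pairs of an hs1262 with an hs1467 library, with 6 and 1 segments, and the other 10 had 0. For hs1262, with 0 segments, all 12 mixed sets had as many. Without the run 3 libraries, which was chosen after the data had been seen, the counts were 13 in mm1179, 108 in hs72, 1 in hs1262, 8 in hs1467, 3 in hs1586 and 5 in hs1603, and without mm1179 replicate 4 there were 114 in mm1179. Leaving out run 3 leaves only replicate 2 of hs1262, hs1467, hs1586 and hs1603. With 12 mixed sets no line of 2 libraries could have passed the threshold. The length of the longest segment was compared only after the data had been seen. In mm1179 it was 6 tiles, against at most 3 in the 88 mixed sets (exact rank p = 0.0112). In hs1467, hs1586 and hs1603 it was 5, 4 and 7 tiles, and 1 of 12 mixed sets reached as far, the pair of hs1262 replicate 1 and hs1467 replicate 2 with 9 tiles (exact rank p = 0.154). In hs72 it was 3 tiles, which 4 of 12 mixed sets reached (exact rank p = 0.385).

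Segments called only in a line numbered 0 in mm1179, 50 in hs72, 433 in hs1262, 313 in hs1467, 261 in hs1586 and 188 in hs1603. The longest was 2.5 kb on chromosome 9 from 41596501 to 41599000 in hs1586 (percentile 70.2). Several were 2 kb long, and among the named ones that on chromosome 17 from 5037501 to 5039500 in hs1262 had the highest percentile, 49.6. Mixed sets gave as many in 5 of 12 cases for hs72 and for hs1262, 7 of 12 for hs1467 and hs1586 and 9 of 12 for hs1603. The exact rank p ranged from 0.462 for hs72 and hs1262 to 1 for mm1179. With fewer libraries to match, the number of tiles can only rise, though added tiles can join neighbouring segments. Without replicate 1 of the line the segment counts were 1642 in hs72, 9822 in hs1262, 8891 in hs1467, 5723 in hs1586 and 3456 in hs1603. Without replicate 2 they were 1266, 1817, 1556, 1764 and 2696. Without mm1179 replicate 2 there were 2 in mm1179. Without run 3, chosen after the data had been seen, there were 78 in hs72, 11927 in hs1262, 11117 in hs1467, 7063 in hs1586 and 4012 in hs1603. The counts of hs1262, hs1467, hs1586 and hs1603 then rest on replicate 2 alone.

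Pairs of libraries of 1 genotype shared a mean Jaccard index of 0.577 ± 0.064 (SD, 17 pairs), and pairs of different genotypes 0.539 ± 0.094 (SD, 136 pairs). The difference of 0.0378 had p = 0.0543 in a one-sided permutation test of the genotype labels. Within runs it did not hold, with a permutation p of 0.701 when labels moved within runs only. Pairs of the same run had an index of 0.653 ± 0.047 (SD, 33 pairs) and pairs of different runs 0.513 ± 0.077 (SD, 120 pairs). Within run 1 the index was 0.616 for pairs of 1 genotype and 0.617 for pairs of different genotypes. Within run 2 these were 0.642 and 0.640, and runs 3 and 4 held no pair of 1 genotype. The pooled p was 0.0411 with peaks scoring at least 100 and 0.0329 without replicate 2, with labels moved across runs in both. Leaving out replicate 2 removes all of run 4. Only wild type and mm1179 then keep pairs of 1 genotype, and run 3 enters only in pairs of different genotypes. That p therefore cannot tell genotype from run.

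**Figure D3:**
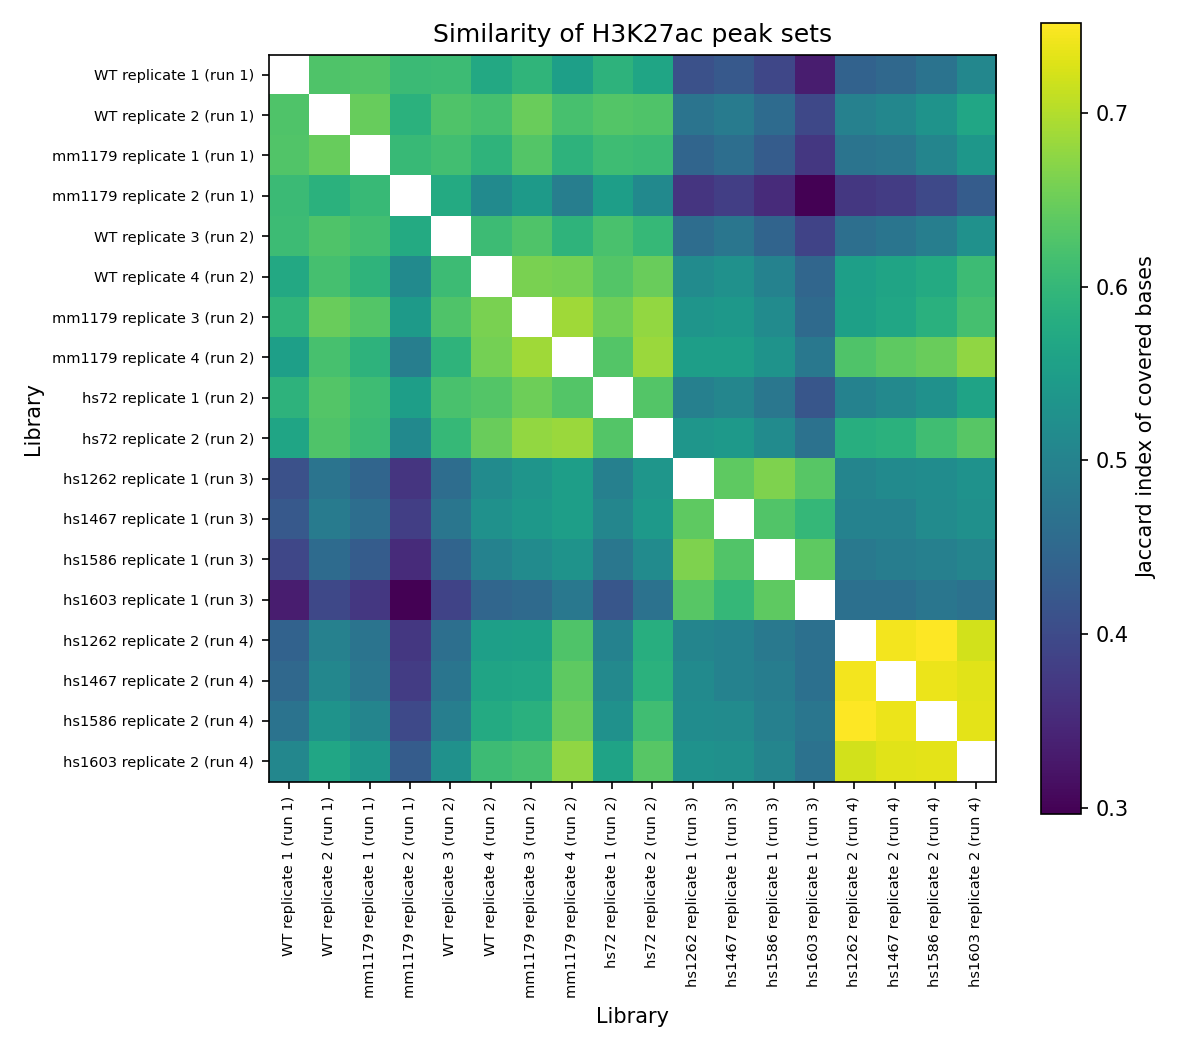
Jaccard index of the bases covered by peaks for every pair of the 18 libraries, ordered by run, on both axes. The 6 pairs within run 4 average 0.737, and the 4 same-genotype pairs between runs 3 and 4 average 0.492.

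Most wild-type regions were retained in the hs72 line and in the run 4 libraries. The hs72 libraries called 95.3% ± 2.0 of them (SD, n = 2). Replicate 2 of hs1262, hs1467, hs1586 and hs1603, all of run 4, called 99.8%, 99.8%, 99.7% and 99.7%. These exceed the 93.5% of wild-type libraries themselves. The run 4 peaks covered 140.9 to 166 Mb, against 75.8 to 101.7 Mb in wild-type libraries. An overlap of 1 bp counts as a call, so a broader list can retain more. Replicate 1 of the same lines, all of run 3, called 69.8%, 70.2%, 66.2% and 59.9%. The means were 84.8% ± 21.2 for hs1262, 85.0% ± 20.9 for hs1467, 83.0% ± 23.7 for hs1586 and 79.8% ± 28.1 for hs1603 (SD, n = 2 each). Retention was not tested, and the smallest p that 2 against 4 libraries can give is 0.0667.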

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

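Leaving out run 3 and permuting labels within runs on equal lists were chosen after the data had been seen. Without run 3, values of hs1262, hs1467, hs1586 and hs1603 rest on replicate 2 alone. Of 183 alternative values, 100 kept their direction and side of the threshold or stayed within the set range, 76 moved, 5 turned in sign and 2 passed a threshold that the main value did not. The cause was not tested, except that counts of regions and of tiles can only rise when fewer libraries must match, as when a library or run 3 is left out. Added tiles can join neighbouring segments, so the number of segments is not bound to rise. Depth limits all counts in a way that the lists do not show.

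The mm1179 minus wild-type difference in peaks was -1726 and became 42 with a minimum score of 100 (p = 0.971, exact permutation). Leaving out 1 library gave -4250 to 599, with 16.2 without WT replicate 4. The difference in covered length was 2.74 Mb and ranged from -6.05 to 11.5 Mb with 1 library left out, with -0.731 without WT replicate 1. No p of these was under 0.05. Same-numbered wild-type and mm1179 libraries share a run as well as a number. Their deviations correlated at 0.0139 to 0.0953, and 1 of 4 wild-type libraries correlated best with its own number. Every correlation within a run was positive, from 0.0139 to 0.0953, and every one across runs was negative, from -0.095 to -0.0195. The correlations thus followed the run and not the number. With the replicate block, p was 0.625 for peaks (-1726) and 0.875 for covered length (2.74 Mb), and the counts of 42 and 19 separated regions had block p of 0.625 and 1, so the block changed no call.

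The similarity difference was 0.0534 with a minimum score of 100 (permutation p = 0.0411). With 1 replicate number left out it ranged from 0.00608 to 0.0829 (permutation p of 0.441 and 0.0329). On equal lists with labels permuted within runs, p was 0.448, and without run 3 it was 0.169.

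Wild-type-only regions numbered 13 with a minimum score of 100, 26 on equal lists, 27 with at least 50% of the region covered, and 53 to 196 with 1 library left out. The mm1179-only regions numbered 14 with a minimum score of 100, 35 on equal lists, 28 with at least 50% of the region covered, and 25 to 156 with 1 library left out. With the minimum score, on equal lists and with 50% covered, the wild-type-only count was below the mm1179-only count, unlike the main 42 against 19.

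Lost segments with a minimum score of 100 numbered 6 in hs72. On equal lists they numbered 9 in mm1179, 18 in hs72 and 4 in hs1586. When 90% of the other libraries sufficed they numbered 57 in mm1179, 117 in hs72, 2 in hs1467 and 2 in hs1603. Without run 3 they numbered 13 in mm1179, 108 in hs72, 1 in hs1262, 8 in hs1467, 3 in hs1586 and 5 in hs1603. With 1 replicate of the line left out they ranged from 3 to 114 in mm1179, 111 to 478 in hs72, 0 to 151 in hs1262, 1 to 125 in hs1467, 2 to 271 in hs1586 and 4 to 1288 in hs1603, highest without replicate 2 in the lines of 2 libraries and without replicate 4 in mm1179. A segment already lost stays lost by construction when a replicate of its line or run 3 is left out or when 90% of the other libraries suffice, so these settings say nothing of its stability. Under the others, a minimum score of 100, equal lists and tiles of 1000 bp, the longest segments of mm1179, hs1467, hs1586 and hs1603 were still lost. That of hs72 was lost with tiles of 1000 bp, where it was not the longest, and not under the other 2. A minimum score and equal lists only remove peaks, so they ask only whether the peaks of the other libraries pass the cut.

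Gained segments with a minimum score of 100 numbered 13 in hs72, 225 in hs1262, 138 in hs1467, 127 in hs1586 and 92 in hs1603. On equal lists they numbered 1 in mm1179, 19 in hs72, 130 in hs1467 and 99 in hs1603. With tiles of 1000 bp they numbered 235 in hs1262, 194 in hs1467, 157 in hs1586 and 114 in hs1603. When 10% of the other libraries were allowed they numbered 135 in hs72, 1430 in hs1262, 950 in hs1467, 867 in hs1586 and 658 in hs1603. Without run 3 they numbered 78 in hs72, 11927 in hs1262, 11117 in hs1467, 7063 in hs1586 and 4012 in hs1603. With 1 replicate of the line left out they ranged from 0 to 2 in mm1179, 1266 to 1642 in hs72, 1817 to 9822 in hs1262, 1556 to 8891 in hs1467, 1764 to 5723 in hs1586 and 2696 to 3456 in hs1603. Retention in the knockout lines moved by less than 1 SD with a minimum score of 100, on equal lists and with at least 50% of a region covered, while that of wild type, 93.5% ± 2.8 (SD, n = 4), was 90.4% with at least 50% covered, a move of over 1 SD. In a line of 2 libraries, leaving out 1 cannot move it by more than 1 SD, so that setting says nothing of stability, and in hs1603 it gave 59.9% and 99.7%. The promoter comparison was not run, for want of an annotation of the build.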

Other observations

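The count over splits of the libraries was planned. All other tests in this part were chosen after the data had been examined, and what each was expected to show, the splits included, was written down only after the tests had first been run.

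Within 1 Mb of the longest lost segments, and leaving out any region that overlaps the segment itself, no region called in all 4 wild-type libraries was missing from every library of the line. This covered 15 regions in mm1179, 20 in hs72, 27 in hs1467, 15 in hs1586 and 29 in hs1603, and since 0.0476% to 0.674% of such regions were missing elsewhere in the genome, none would be expected among so few. The share called in every library of the line was 80% near the segment and 84.1% elsewhere in mm1179, and 90% and 94.3% in hs72. It was 77.8% and 70.4% in hs1467, 80% and 66.7% in hs1586, and 75.9% and 59.6% in hs1603, and these shares were not tested. That loss of a segment may go with changed calls nearby was a hypothesis, tested on regions missing from the whole line and on regions newly called in it. Regions without a wild-type call were newly called in every library of the line at 15.8% near the segment and 8.77% elsewhere in hs1603, 7.14% and 6.74% in hs1586, 10.3% and 11.9% in hs1467, 0% and 4.41% in hs72, and 0% and 0.127% in mm1179. Over 10 one-sided Fisher's exact tests in 5 lines, the smallest Benjamini-Hochberg adjusted p was 1. The regions were few and not independent, and in hs1467, hs1586 and hs1603 runs were tied to genotype, so a change stays open.

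The 61 regions that separated mm1179 from wild type could come from chance. Of the 35 splits of the 8 libraries, 27 gave as many, so chance cannot be excluded. The highest other split gave 424 and was the split by run, which points to a structure of the samples. Among the 18 splits balanced over the runs, 11 gave as many, and the highest other gave 129.

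The 4 run 3 libraries called no peak at 4469 of the 19035 regions that all 10 libraries of runs 1 and 2 called. Lower depth, which loses weak peaks first, is a candidate explanation. In wild type, 48.1% of the regions that all run 3 libraries called scored below the median of the missed ones. The bound for depth alone, the lowest 25%, was set by hand after the values were seen. A measured reference is mm1179 replicate 2, the shortest list of runs 1 and 2, whose depth is also unknown. Of the regions that every other library of those runs called, the ones it missed had a median percentile of 42.4, and the ones it called 72.7. The missed regions were narrower, with a median width of 3014 bp against 4019 bp. Peaks of run 3 helped set the width of the regions it called, and averaged 2801 to 3374 bp per library. In runs 1 and 2 the averages were 2039 to 2568 bp, so part of the width difference can be built in. The median percentile of the missed regions was 70.2 against 71.3 (bootstrap interval of the difference -1.91 to -0.127). The interval treats regions as independent and does not measure the spread between libraries or runs. Both differences lie in the direction of lower depth, but neither is a test of it. However, the run 3 libraries called 61.9% to 91.3% of the 1000 highest wild-type regions, and every other library called 100%. These values argue against loss of weak peaks as the whole explanation, while a part played by depth stays open. Genotype is argued against too, since each run 4 library of the same lines called at least 99.98% of the missed regions. Also open is a bias of the run, such as one by base composition, which was not tested, and the longest stretch missing in run 3 alone was 39.5 kb on chromosome 6 from 52165501 to 52205000.

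Gaps crossed the labels hs1262 and hs1467. A stretch of 1.5 kb on chromosome 14 from 29911501 to 29913000 was uncalled in hs1262 replicate 2 and hs1467 replicate 1 alone, and 5 segments on chromosome 4 between 106645501 and 106662500 in hs1262 replicate 1 and hs1467 replicate 2 alone, all noticed after their values were seen. With the 2 labels exchanged in 1 run, a possible explanation, the sum of the longest lost segments over the 4 lines was 23 tiles and as labelled 16, but the rise comes from these same crossed gaps and adds no evidence of its own. Against it, both libraries labelled hs1467 lacked the 5 tiles on chromosome 11, which an exchange would not leave together. Exchanged and correct labels therefore cannot be told apart from these lists, and the deleted coordinates, which would decide it, were not used here.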
